A study of Homo sapiens with 6 samples.

How the data were processed

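RNA sequencing was carried out on 6 samples of 2 human melanoma cell lines, A375 and WM266.4, each transduced with a scrambled short hairpin RNA or with a hairpin against LSD1 or JMJD2C. Each of the 3 treatments was labelled once in each line, so a treatment has 2 samples and a line-by-treatment combination has 1. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made by a sequencing provider. The submitters' processing notes list STAR, SAMtools 0.18, DESeq2 and the genome build GRCh38, with no role or order. The read counter and the gene annotation are not given in the sources used here.

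The authors deposited a table of counts per gene and a table on a regularized log2 scale. The scales were inferred from the range and form of the values and from the names of the tables, and the values were put to no other use. In each table, the parts of the 6 value column names were read as a sequencing run, a lane or second run, and a barcode number. That reading rests on the form of the names. None of the 6 column names, and none of the run names within them, occurs in the titles, characteristics, protocols or design text. With the sources used here, a column could be assigned to a treatment or a cell line only from its position or from its expression values, and a key from barcode to sample was not among them. Assigning by expression, for instance by looking for the column with the lowest KDM1A, would make the outcome define the groups. No such assignment was made, and the 6 columns of each table entered no computation. The depth per sample is not reported here for the same reason.

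The planned comparisons, fixed before the data were examined, were count-model tests of each knockdown against control with cell line as a block, a direct test between the knockdowns, a test between the lines, and gene list tests. None of these tests was run, none of their alternative settings was computed, and no rule for naming genes by their change was applied.

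What was analysed is the set of gene identifiers that each table lists. Ensembl gene identifiers were read with Python 3.11.15 and pandas 2.3.3 and matched without version numbers to a table of gene names and to GENCODE 29, an annotation of GRCh38 that is not known to be the one the authors used. Of the 58233 identifiers in the counts table, 57392 had a symbol in the name table and 57895 were in GENCODE 29. The 32 gene lists were fixed before the data were examined, the ZNF list as a rule and the others by member. The ZNF rule as fixed took its members from the tested genes. As no gene was tested, ZNF members here were the genes of the counts table whose current symbol was ZNF followed only by digits. All of them are in that table by construction. Members of the other lists were matched on the current symbol, then on the GENCODE 29 symbol, then on a synonym. Synonyms were those that NCBI RefSeq's gene table (GRCh38.p14, used for names only) gives to a single gene. Names of the same gene were counted once. Gene coordinates are those of GENCODE 29, counted from 1.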

Results

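The study profiled gene expression in 2 melanoma cell lines, A375 and WM266.4, after knockdown of a histone demethylase. LSD1, encoded by KDM1A, and JMJD2C, encoded by KDM4C, are enzymes that remove methyl groups from histone H3 lysines. Short hairpin RNAs against either gene were set against a scrambled hairpin. The labels give 2 samples for shControl, 2 for shLSD1 and 2 for shJMJD2C, in each case 1 in A375 and 1 in WM266.4.

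The design implies a comparison of each knockdown with control across the lines, a comparison between the knockdowns, and a comparison between the lines. The number of these comparisons analysed here is 0, because none of the 6 value columns of either deposited table could be matched by name to a labelled sample. No expression level, fold change or test is therefore reported for any treatment or line, including the level of KDM1A or KDM4C that would check the knockdowns.

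Both targeted genes were listed in both tables. KDM1A (ENSG00000004487) is a protein-coding gene on the plus strand of chromosome 1, from 23019443 to 23083689 in GRCh38. KDM4C (ENSG00000107077) is a protein-coding gene on the plus strand of chromosome 9, from 6720863 to 7175648 in the same build.

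The counts table listed 58233 genes. On the regularized log2 scale 31937 genes were listed, all of them also in the counts table. The other 26296 genes were in the counts table alone. By GENCODE 29 gene type, 17427 of 19791 protein-coding genes (88.1%) were in the regularized log2 table, against 3470 of 7315 lincRNA genes (47.4%) and 3874 of 10180 processed pseudogenes (38.1%). The rule by which genes entered the regularized log2 table was not tested here. A listed gene is not thereby shown to be expressed in any given sample, and a gene left out is not shown to be unexpressed.

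For 22 of the 32 gene lists fixed for this design, every member was in the regularized log2 table. These included the 57 DNA replication and E2F target genes and the 59 genes of mitosis and G2/M. The 60 interferon response genes and the 66 nuclear-encoded oxidative phosphorylation genes were also complete. So was the list named lysine demethylases, whose 28 members include HIF1AN, JMJD6 and JARID2 beside the KDM genes. The other 10 lists each had at least 1 member in the counts table alone. Of the 40 pigmentation and MITF target genes, 38 were in the regularized log2 table. The remaining pair, SOX10, a transcription factor of the neural crest and melanocyte lineage, and KIT, a receptor tyrosine kinase of melanocytes, were in the counts table alone. Of the 48 cancer-testis antigen genes, 47 were matched in the counts table and 39 in the regularized log2 table. The name BAGE matched no listed gene. Those in the counts table alone were XAGE1A, CTAG1B, SSX2, SSX4, CSAG2, SYCP1, DAZL and TDRD1. Of the 477 genes of the counts table whose symbol is ZNF followed only by digits, 472 were in the regularized log2 table. Of the 24 genes listed as lymphoid and myeloid markers, 22 were in the regularized log2 table, all but CD2 and the hemoglobin gene HBB. So were 18 of 19 fibroblast marker genes. All 25 epithelial and keratinocyte genes and all 14 HEK293 and packaging-cell genes were in it as well. Of all protein-coding genes 88.1% were in it, and the marker counts were not tested against that share. All of the above are counts of listed genes, with no error and no comparison between samples. Absence from the regularized log2 table does not show that a gene was not expressed, SOX10, KIT and the cancer-testis antigen genes included.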

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

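No paired analysis was run because the value columns carry no sample, treatment or cell line name. None of the alternatives planned for the comparisons was run for the same reason. Without assigning columns by position or expression, a key from barcode number to sample would be needed before any of these could be run. The only setting varied, chosen after seeing the data, was the matching of list members by symbol. With current symbols only, 15 of the 32 lists had every member in the regularized log2 table, against 22 with the GENCODE 29 symbols and RefSeq synonyms added. The difference comes from names that did not match, not from genes left out of the table. The members found there, summed over lists, were 1535 and 1588.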
